A study of Drosophila melanogaster with 4 samples.

How the data were processed

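The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the Drosophila transcription factor Ribbon (Rib) fused to GFP. The transgene, under UAS control, was expressed with the fkh-Gal4 or the sage-Gal4 driver. Per the labels, embryos of stages 11 to 16 came from an 8 h collection aged for 11 h, were sorted by machine and were cross-linked in 1.8% formaldehyde. An anti-GFP antibody was used for the immunoprecipitation, and 50 bp reads were sequenced. The 4 samples are 1 immunoprecipitation and 1 input per driver, and each merges 3 collections, per the labels. Read-level data of the inputs were not used here.

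What the authors deposited for each driver and what was read here is a list of peak positions with 3 columns, the chromosome, the start and the end. The lists hold no height, fold enrichment, p-value, score or summit. BWA, MACS2 2.1.0.20140616 and the genome build dm6 are named in the submitters' processing notes. The version of BWA, the peak threshold, the treatment of reads that map to several places and the filters are not given in the sources used here, nor whether the inputs served as the control of the peak calls. Because the collections were merged, there is 1 list per driver and no replicate error. The lists carry no read counts, so the depth of each library is unknown, and a peak missing from a list is not shown to be absent from the embryos. Each p-value and interval below treats peaks or genes as the counted units and describes these lists only.

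Starts were converted from a 0-based to a 1-based count. Gene positions came from a RefSeq gene table of the same assembly, which gives each gene's start and end but neither its strand nor its transcript starts. Promoters therefore could not be told from 3′ ends. The test planned for transcription start sites was run on both ends of each gene instead, and a gene is called bound where a peak overlaps the 1 kb on either side of either end. The background was the 13946 protein-coding genes on chromosomes 2, 3, 4, X and Y, and these windows cover 24.0% of that genome. A peak can bind several neighbouring genes in this sense, so genes are not independent of each other. A search for 13 sequence motifs at peak centres was planned and was not run, because no genome sequence was used here. The peak value planned for ranking was fold enrichment or a score; with neither in the lists, peak width took its place, as the plan allowed.

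The share of peaks at a gene end and the share of sage-Gal4 peaks that overlap a fkh-Gal4 peak by at least 1 bp were set against 1000 circular rotations of the peaks along their chromosome arm. The smallest two-sided p these rotations can give is 0.002. The alternatives by reciprocal overlap and by peak centres used 200 rotations. Intervals are exact (Clopper-Pearson) at 95% and cover counting error only. Each of 20 gene lists fixed before the data were examined was compared with all other genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Symbols or older symbols matched all but 1 asked name of the salivary gland list, 1 of the germline list and 2 of the secretory list. A gene may sit in several lists, as 9 of the 25 salivary gland genes do. To ask which gene lists were shared between the drivers more or less often than other genes, the same test compared genes bound in both lists with genes bound in the fkh-Gal4 list alone. Widths were compared by a two-sided permutation test with 100000 resamples. Small RNA genes were compared with the rotated peaks, with Benjamini-Hochberg adjustment over 5 classes in 2 lists; tRNA and snRNA genes were planned, and snoRNA, miRNA and 5S rRNA genes were added after the data were seen.

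The genes named in the text follow a rule fixed before the data were examined. They are rib, fkh, sage, lolal and CrebA; the 15 genes bound in both lists, the 10 bound in the fkh-Gal4 list alone and the 10 bound in the sage-Gal4 list alone with the widest peaks; and up to 4 bound members of each gene list. Histone genes filled the first 2 of these rankings, which were repeated without them after the data were seen. List members named beyond these 4, and the loci picked out in the other observations, were chosen after their values were seen and are marked so.

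The alternatives were the wider peaks of each list (split at the median width), the major arms 2L, 2R, 3L, 3R and X alone, merging of peaks within 500 bp, windows of 500 bp and 2 kb, assignment of each peak to its nearest gene end, a reciprocal overlap of 50%, peak centres within 200 bp, and a fkh-Gal4 list cut to the 907 widest peaks. Leaving out the histone and 5S rRNA gene arrays, counting peaks anywhere in the gene body extended by 1 kb, and thinning the fkh-Gal4 list at random were added after the data were seen. Because long genes meet more peaks over their bodies, the gene-body counts were then also set against 10000 random lists that took, for each member, 1 of the 100 genes nearest in length outside the list. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The gene list test and the overlap test were tested on simulated data with 13946 genes. On peak lists rotated at random along their arms, 0 of 380 list tests passed the threshold for the fkh-Gal4 comparison and 1 of 380 for the sage-Gal4 comparison. The histone list was left out of these counts, so they say nothing about tests of that list. A planted list was recovered in 20 of 20 runs for each.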

Results

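Rib is a nuclear protein with a BTB domain and a Pipsqueak DNA-binding domain that is needed for the elongation of the salivary gland and the trachea. It was tagged with GFP and expressed in the embryo with 2 drivers, fkh-Gal4 and sage-Gal4, both of which are used to express transgenes in the embryonic salivary gland. ChIP-seq with an anti-GFP antibody gave 1 merged peak list per driver, from 3 merged collections each. No value below has a replicate error, and the read depth behind the lists is unknown. The fkh-Gal4 list held 4196 peaks with a median width of 122 bp (range 70 to 1598) that covered 712.8 kb. The sage-Gal4 list held 907 peaks with a median width of 102 bp (range 57 to 382) that covered 105.6 kb.

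The first comparison asked where in the genome the tagged protein was found. In the sage-Gal4 embryos, peaks gathered at gene ends: 382 of 868 peaks on chromosomes 2, 3, 4, X and Y (44.0%, 95% interval 40.7 to 47.4) lay within 1 kb of an end of a protein-coding gene, against a mean of 25.4% for rotated peaks (two-sided permutation p = 0.002, the smallest possible). In the fkh-Gal4 embryos, 896 of 3372 peaks did so (26.6%, 25.1 to 28.1), and the rotated peaks gave 25.1% (permutation p = 0.25). Peak centres lay inside gene bodies less often than rotated ones in both lists, at 53.2% against 65.6% for fkh-Gal4 and 57.3% against 66.5% for sage-Gal4 (permutation p = 0.002 for each). The fkh-Gal4 share at gene ends moved with the window, from 22.4% (permutation p = 0.002, above rotated peaks) at 500 bp to 32.5% (p = 0.026, below rotated peaks) at 2 kb.

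Peaks outside the major arms were far more common in the fkh-Gal4 list. There, 988 of 4196 peaks (23.5%, 22.3 to 24.9) lay on chromosome 4, the Y, the mitochondrial genome or unplaced scaffolds, against 55 of 907 (6.06%, 4.60 to 7.82) in the sage-Gal4 list (odds ratio 4.77, Fisher's exact p = 2.62e-39). Chromosome Y, which is rich in repeats, carried 127 fkh-Gal4 and 9 sage-Gal4 peaks. Scaffolds with no assigned position carried 820 and 38.

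**Figure D1:**
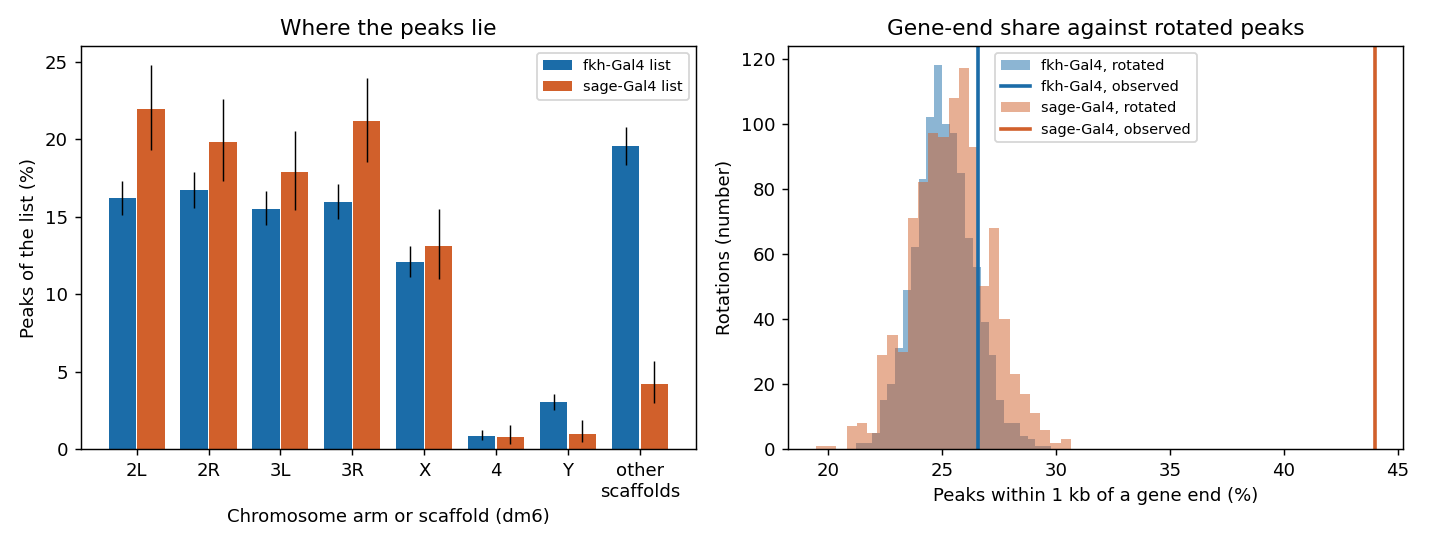
Left, the percentage of each driver's peaks on each chromosome arm of dm6 and on all other scaffolds, with exact 95% intervals; fkh-Gal4 peaks are blue and sage-Gal4 peaks orange. Right, histograms of the percentage of peaks within 1 kb of a gene end over 1000 rotations, with the observed values as vertical lines at 26.6% (fkh-Gal4) and 44.0% (sage-Gal4).

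The next comparison asked which genes the protein met in the fkh-Gal4 embryos, where 1192 of 13946 protein-coding genes (8.55%) were bound. Genes for cytoplasmic ribosomal proteins stood out, with 57 of 86 bound (66.3%, 55.3 to 76.1) against 8.19% of other genes (odds ratio 22, Fisher's exact test, adjusted p = 2.23e-39). Both subunits contributed, with 33 of 48 genes of the large and 24 of 38 of the small subunit. Embryonic salivary gland genes were also bound more often than other genes (9 of 25, 36.0%, 18 to 57.5, odds ratio 6.06, adjusted exact p = 5.47e-04), as were genes of epithelial polarity and morphogenesis (8 of 36, 22.2%, 10.1 to 39.2, odds ratio 3.07, adjusted exact p = 0.0277). Among 20 lists, 5 were bound more and 2 less often than other genes.

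At ribosomal protein genes the peaks sat close to the gene end. The median distance from the peak centre to the nearer end was 22 bp (quartiles 10 and 40) over the 57 bound genes. Over the other 1024 bound genes, histones left out, it was 230.25 bp (quartiles 44.4 and 582). These others include neighbours counted through a ribosomal protein gene's own peak, such as CG13690 and CG11885 through that at RpLP1. The contrast may therefore partly reflect how peaks were assigned to genes. Peaks spanned an end of RpL41 (2R, 24903845 to 24904027, 183 bp), of RpS10b (X, 19597923 to 19598149, 227 bp) and of RpL22 (X, 765025 to 765242, 218 bp), while that at RpL30 ended just inside the gene (2L, 19009161 to 19009296, 136 bp). The call held with the wider peaks alone (45.3%, adjusted exact p = 2.94e-29). It was lost in the list of the 907 widest fkh-Gal4 peaks, which met 100% of histone genes and 2.33% of ribosomal protein genes (adjusted exact p = 1). With no measure of strength in the lists, whether the widest peaks are the strongest is unknown, so that loss cannot be read as a lack of stability among strong peaks.

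The salivary gland genes bound included transcription factors, genes of morphogenesis and enzymes. A peak of 153 bp overlapped an end of CrebA (3L, 15535252 to 15535404), which encodes a bZIP activator of secretory pathway genes. Others lay at pip (3L, 19337596 to 19337763, 168 bp), a sulfotransferase of the gland, at 18w (2R, 20111440 to 20111604, 165 bp), a Toll family receptor, and at hairy (symbol hry, 3L, 8675657 to 8675782, 126 bp), a transcriptional repressor. The gene fkh itself, a FoxA transcription factor, had an 86 bp peak (3R, 28585602 to 28585687) outside its annotated end. The remaining bound members were crb and, named after their values were seen, sano, klar and PH4alphaSG2. Of the polarity genes, crb (3R, 24295123 to 24295231, 109 bp), which sets the apical membrane, the septate junction gene Fas3 (2L, 18320026 to 18320166, 141 bp) and Rok were bound, as were chic, zip, mys, Moe and baz, which were named after their values were seen. The polarity list fell below other genes with the wider peaks alone (2.78%, adjusted exact p = 1). It was no longer past the threshold with a 2 kb window (22.2%, adjusted exact p = 0.145) or when peaks anywhere in the gene body extended by 1 kb were counted, an alternative added after the data were seen (25%, adjusted exact p = 0.0616).

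Heat shock genes and histone genes made up the other lists bound more often. Of 21 heat shock genes, 11 were bound (52.4%, 29.8 to 74.3, odds ratio 11.9, adjusted exact p = 1.79e-06), among them copies of Hsp70 and, named after their values were seen, Hsp83, Hsp26 and DnaJ-1, which encode chaperones. A peak of 396 bp (3R, 12505534 to 12505929) overlapped an end of Hsp70Bb, lay within 1 kb of Hsp70Bbb and counted for both. All 111 replication-dependent histone genes were bound (100%, 96.7 to 100, adjusted exact p = 4.25e-120). They stand in 1 tandem array on 2L (21416953 to 21541681), in which 120 fkh-Gal4 peaks covered 51.8% of the sequence. The copies of histone and Hsp70 genes are nearly identical, so which copy a read came from is uncertain, and genes that share peaks are not independent.

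Chemosensory receptor genes and cuticle protein genes were bound less often than other genes in the fkh-Gal4 list. Of 179 odorant, gustatory and ionotropic receptor genes, 2 were bound (1.12%, 0.136 to 3.98, adjusted exact p = 1.77e-04), Ir31a and Ir68b. The peak counted for Ir31a lay outside that gene and overlapped an end of the ribosomal protein gene RpS27A and of Ip259, for which it also counted. Of 95 cuticle protein genes, 1 was bound (1.05%, 0.0266 to 5.73, adjusted exact p = 0.0154), Cpr76Ba. The cuticle call was lost when each peak was given to its nearest gene end (1.05%, adjusted exact p = 0.127), and with the wider peaks alone neither call held (adjusted exact p = 0.104 for receptors and 0.330 for cuticle proteins).

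Housekeeping lists other than the cytoplasmic ribosome did not pass. Mitochondrial ribosomal protein genes were bound at 8 of 73 (11.0%, adjusted exact p = 0.558), translation factor genes at 7 of 51 (13.7%, adjusted exact p = 0.449), oxidative phosphorylation genes at 6 of 88 (6.82%, adjusted exact p = 0.740) and proteasome genes at 1 of 38 (2.63%, adjusted exact p = 0.474). Genes of the secretory pathway, through which the gland exports its products, were bound at 3 of 52 (5.77%, adjusted exact p = 0.740), namely Spase22-23, Sec61alpha and Calr. Markers of other tissues did not pass at gene ends either. Tracheal genes were bound at 3 of 17 (uif, bnl and serp), gut genes at 2 of 14 (bowl and fkh), neural genes at 2 of 20 (sca and Syt1), and segmentation and Hox genes at 3 of 21 (hry, odd and slp1). Counts were 0 of 24 for muscle, 0 of 16 for hemocyte and 0 of 10 for germline genes, with upper 95% bounds of 14.2%, 20.6% and 30.8%. Genes for BTB and Pipsqueak-domain factors, the family of Rib, were bound at 2 of 17 (ken and mod(mdg4)), with an adjusted exact p of 0.740. A 2 kb window took this list past the threshold (35.3%, adjusted exact p = 0.0247), and counting peaks over the extended gene body took both it (70.6%, adjusted exact p = 1.33e-07) and the neural genes (40%, adjusted exact p = 0.00287) past it. Long genes meet more peaks in such a count, and the 8 neural genes lay within the central 95% of random lists of genes of nearly the same length (mean 6.03, 3 to 10), whereas the 12 BTB and Pipsqueak-domain genes lay above it (mean 7.10, 4 to 11).

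In the sage-Gal4 embryos, 566 of the 13946 genes (4.06%) were bound, and ribosomal protein genes again led. Of 86, 55 were bound (64.0%, 52.9 to 74.0) against 3.69% of other genes (odds ratio 46.3, Fisher's exact test, adjusted p = 3.16e-54), with 35 of 48 in the large and 20 of 38 in the small subunit. The median distance from peak centre to gene end was 23.5 bp at these genes and 181.5 bp at the other 477 bound genes, histones left out. Those others again include neighbours counted through a ribosomal protein gene's peak. The widest sage-Gal4 peak among the ribosomal protein genes, 288 bp, lay at RpL30 (2L, 19009120 to 19009407). Histone genes were bound at 34 of 111 (30.6%, 22.2 to 40.1, odds ratio 11.0, adjusted exact p = 4.07e-20) through 15 peaks in the array. Heat shock genes were bound at 6 of 21 (28.6%, 11.3 to 52.2, odds ratio 9.55, adjusted exact p = 9.34e-04), namely Hsp70Bbb, Hsp70Bb and Hsp70Bc and, named after their values were seen, Hsp83, DnaJ-1 and Hsp70Ba. With the wider peaks alone the heat shock list was not past the threshold (14.3%, adjusted exact p = 0.0835).

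No other list passed at gene ends in the sage-Gal4 embryos. Salivary gland genes were bound at 2 of 25 (8.00%, 0.984 to 26, adjusted exact p = 0.599), hairy with a 249 bp peak (3L, 8675685 to 8675933) and crb with a 155 bp peak (3R, 24294966 to 24295120). Polarity genes were bound at 4 of 36 (11.1%, adjusted exact p = 0.189), crb, Rok, scrib and, named after its value was seen, fog. Translation factor genes were bound at 5 of 51 (9.80%, adjusted exact p = 0.189), among them eEF1gamma (3R, 29220026 to 29220278, 253 bp) and eEF1alpha1 (2R, 11892070 to 11892231, 162 bp). The receptors were bound at 2 of 179 (1.12%, adjusted exact p = 0.189) and cuticle proteins at 1 of 95 (1.05%, adjusted exact p = 0.471). Counts in the remaining lists were 4 of 73 for mitochondrial ribosomal proteins, 3 of 88 for oxidative phosphorylation, 0 of 38 for the proteasome and 1 of 52 for the secretory pathway. They were 2 of 17 for tracheal genes (bnl and salm), 1 of 14 for gut (drm), 1 of 24 for muscle (sns), 1 of 20 for neural (dpn), 0 of 16 for hemocyte, 1 of 10 for germline (tud), 1 of 21 for segmentation and Hox genes (hry) and 1 of 17 for BTB and Pipsqueak-domain factors (mod(mdg4)). When peaks over the extended gene body were counted, 8 lists passed in place of 3. Salivary gland genes (20%, adjusted exact p = 0.0329), polarity genes (16.7%, adjusted exact p = 0.0355), gut genes (28.6%, adjusted exact p = 0.0210) and BTB and Pipsqueak-domain factors (41.2%, adjusted exact p = 1.36e-04) then joined as bound more often, and the receptors (1.12%, adjusted exact p = 0.0187) as bound less often. All 5 counts lay within the central 95% of random lists of genes of nearly the same length, whose means were 3.63 salivary gland (1 to 7), 4.30 polarity (1 to 8), 1.43 gut (0 to 4), 3.77 BTB and Pipsqueak-domain (1 to 7) and 6.04 receptor genes (2 to 11).

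**Figure D2:**
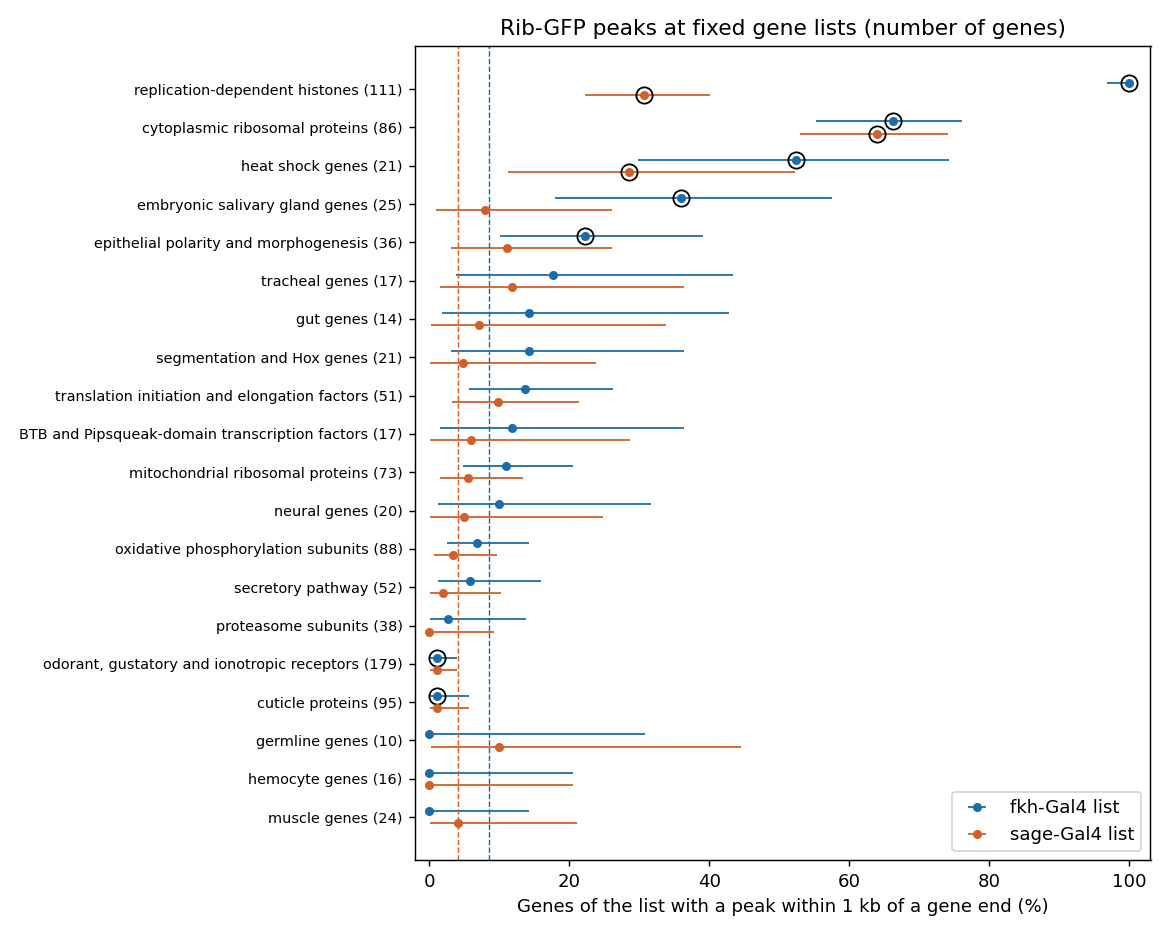
Percentage of the genes of each fixed list (number of genes in brackets) with a peak within 1 kb of a gene end, with exact 95% intervals, for the fkh-Gal4 list (blue) and the sage-Gal4 list (orange). Dashed lines mark the share of all genes, 8.55% and 4.06%, and rings mark lists past the threshold; ribosomal protein genes stand at 66.3% and 64.0%.

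At the loci of the factors behind the experiment, the gene rib (2R, 19270078 to 19281396) had no peak at either end in either list. Inside the gene lay 3 fkh-Gal4 peaks, the widest of 253 bp (19275480 to 19275732), and 1 sage-Gal4 peak of 92 bp (19275669 to 19275760) that overlapped it. The gene sage, a bHLH factor of the gland, and lolal, a small BTB protein, had no peak in their bodies or within 1 kb in either list. CrebA and fkh had a peak in the fkh-Gal4 list and none in the sage-Gal4 list.

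A further comparison asked whether the 2 drivers placed the protein at the same sites. Of the sage-Gal4 peaks, 615 of 907 (67.8%, 64.7 to 70.8) overlapped a fkh-Gal4 peak. On chromosomes 2, 3, 4, X and Y the share was 588 of 868 (67.7%), against a mean of 0.739% and a highest value of 1.96% for rotated peaks (two-sided permutation p = 0.002, the smallest possible). In the other direction, 586 of 4196 fkh-Gal4 peaks (14.0%, 12.9 to 15.1) overlapped a sage-Gal4 peak. With a reciprocal overlap of 50% the sage-Gal4 share was 34.5%, and against the 907 widest fkh-Gal4 peaks it was 29.2%.

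The shared fkh-Gal4 peaks lay at gene ends more often than the rest of that list, at 242 of 561 (43.1%) against 654 of 2811 (23.3%), with an odds ratio of 2.50 (Fisher's exact p = 1.01e-20). In the sage-Gal4 list the shared peaks gave 249 of 588 (42.3%) and the others 133 of 280 (47.5%), a difference that did not pass (odds ratio 0.812, exact p = 0.165). The shared fkh-Gal4 peaks were chosen by overlap with the sage-Gal4 list, of which 44.0% lay at gene ends. Their higher share is thus no separate evidence that peaks common to both drivers favour gene ends. Shared fkh-Gal4 peaks had a median width of 173 bp (quartiles 116 and 328) and the others 116 bp (quartiles 87 and 177), a difference of 57 bp (permutation p = 2e-05, the smallest that 100000 resamples can give). Wide peaks are met more often by chance, and fkh-Gal4 peaks met by rotated sage-Gal4 peaks had a median width of 169.5 bp, close to that of the shared peaks.

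At the level of genes, 410 were bound in both lists where independent lists would share 48.4 (odds ratio 42.3, log10 of the one-sided Fisher p = -331). These were 72.4% of the sage-Gal4 genes. A further 782 genes were bound in the fkh-Gal4 list alone and 156 in the sage-Gal4 list alone. The 15 genes with the widest fkh-Gal4 peak among those bound in both lists, and the 10 among those bound in the fkh-Gal4 list alone, were histone genes of the array on 2L. The widest fkh-Gal4 peak, 1598 bp (21497356 to 21498953), spanned His2B:CG33884 and the ends of His1:CG33840 and His2A:CG33841.

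Ranked again without histone genes, the genes bound in both lists with the widest fkh-Gal4 peaks were CG17698, Rh5, COX7AL2, CG12885, Gnpnat, CG12679, CIA30, CG3655, CG18063, Hsp70Bbb, Hsp70Bb, aqrs, CG33500, Sgs8 and CG32512. The peak near CG17698 was 883 bp (3L, 23736990 to 23737872) in the fkh-Gal4 list and 247 bp (23737234 to 23737480) in the sage-Gal4 list. That near Rh5, which encodes a rhodopsin, was 646 bp (2L, 12007083 to 12007728) and 219 bp (12007429 to 12007647). CG33500 and Sgs8, a glue protein gene of the larval salivary gland, shared a peak of 365 bp (3L, 11507821 to 11508185) with a sage-Gal4 counterpart of 197 bp (11507855 to 11508051). Genes bound in the fkh-Gal4 list alone were led by sl, a phospholipase C (X, 16349261 to 16349790, 530 bp), and syd, a kinesin adaptor (3L, 7916918 to 7917433, 516 bp). Fic, Acox3, alpha-Man-Ia, Ag5r2, CG12446, CG1090, dpr3 and Dsp1 followed.

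Genes bound in the sage-Gal4 list alone were led by the neighbours CG34396 and ktub, which shared a peak of 294 bp (2R, 21101661 to 21101954). CG43131 had a peak of 240 bp (3R, 5108061 to 5108300). A peak of 207 bp (3L, 3336784 to 3336990) covered an end of kst, which encodes the apical beta-heavy spectrin, and lay within 1 kb of the antimicrobial peptide genes Drsl1 and Drsl6. Tom, of the Bearded family of Notch pathway regulators, had a peak of 194 bp (3L, 14969386 to 14969579). The others were betaTub60D (193 bp), Nacalpha (190 bp) and boca (180 bp).

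Ribosomal protein genes were also shared between the drivers more often than other bound genes. Of the 57 with a fkh-Gal4 peak, 51 had a sage-Gal4 peak too (89.5%, 78.5 to 96.0), against 31.6% of the other fkh-Gal4 genes (odds ratio 18.4, Fisher's exact test, adjusted p = 1.78e-17). It was the 1 list of 17 tested that passed. Histone genes gave 34 of 111 (30.6%, adjusted exact p = 0.979), but passed as the less often shared list with the wider peaks alone (13.5%), a 500 bp window (17.1%) and the nearest gene end (7.95%). Of the other lists, heat shock genes gave 6 of 11 (54.5%, adjusted exact p = 0.938), polarity genes 2 of 8 (25%, adjusted exact p = 1) and salivary gland genes 2 of 9 (22.2%, 2.81 to 60.0, adjusted exact p = 1). At gene ends the salivary gland list thus passed in the fkh-Gal4 list and not in the sage-Gal4 list. The test of sharing between the drivers was not past the threshold, but it rested on 9 salivary gland and 8 polarity genes. Their wide intervals (2.81 to 60.0 and 3.19 to 65.1) hold the 34.5% of other fkh-Gal4 genes. With so few genes the test could hardly pass, so a difference is neither shown nor excluded. Over extended gene bodies the salivary gland list passed in both against all other genes, at 52% (adjusted exact p = 4.38e-06) and 20% (adjusted exact p = 0.0329). Against random lists of nearly the same gene lengths, the fkh-Gal4 count of 13 lay above the central 95% (mean 7.46, 4 to 11) and the sage-Gal4 count of 5 within it.

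Both lists had peaks in the histone array, 120 fkh-Gal4 peaks (2.86% of that list) with a median width of 366.5 bp and 15 sage-Gal4 peaks (1.65%) of 101 bp, which covered 1.32% of it; the difference in share was not tested. In the 5S rRNA array on 2R (19729562 to 19766278), 94 fkh-Gal4 peaks (2.24% of that list) covered 44.7% of the sequence and the sage-Gal4 list had 0. All 96 of the 5S rRNA genes tested had a fkh-Gal4 peak within 1 kb (rotated mean 4.85, adjusted permutation p = 0.01, from the smallest p that rotations give), against 0 of 96 in the sage-Gal4 list (adjusted permutation p = 1).

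**Figure D3:**
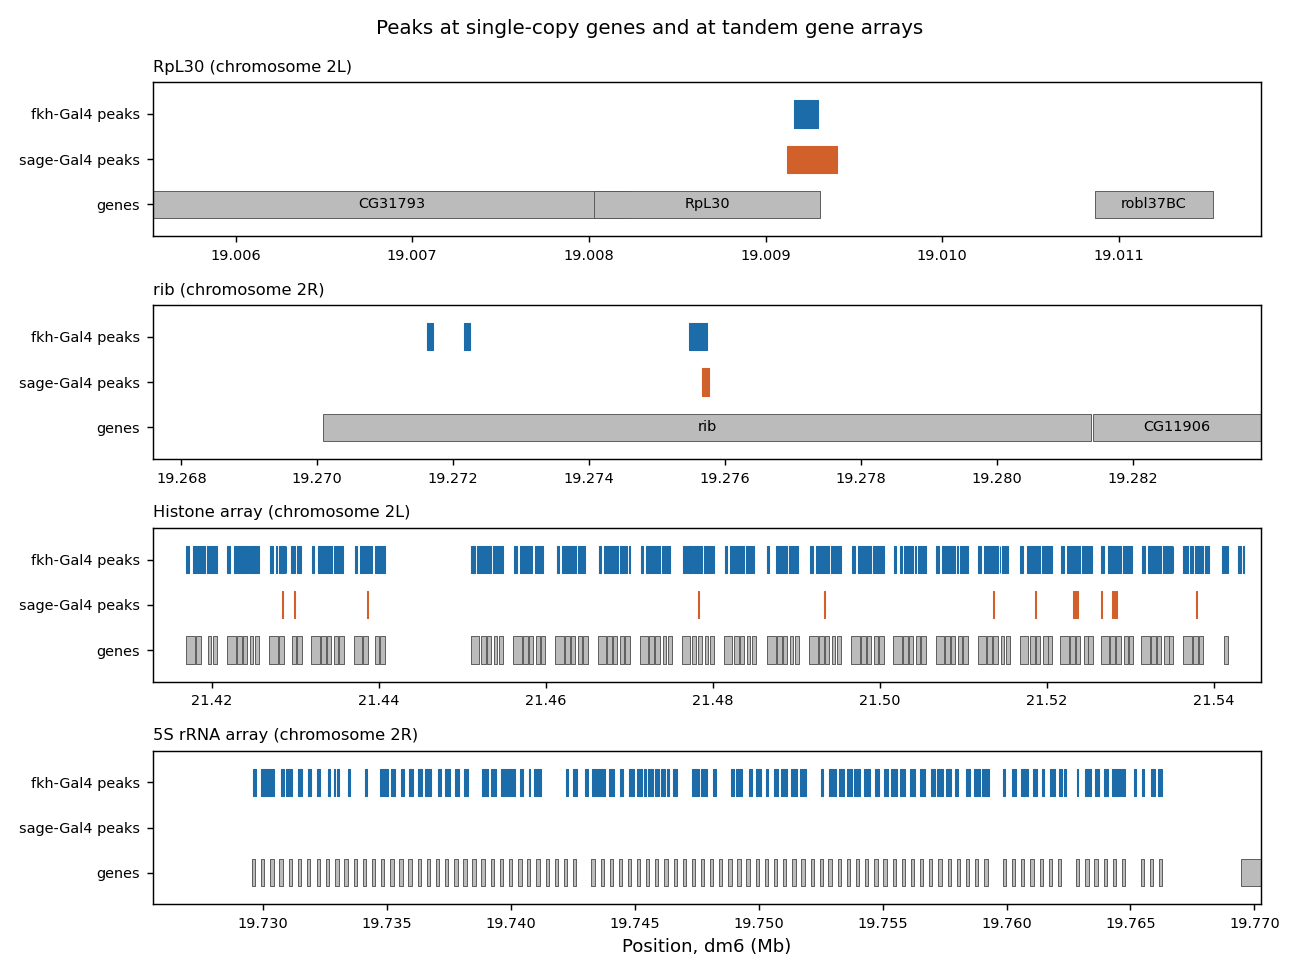
Peaks of the fkh-Gal4 list (blue) and the sage-Gal4 list (orange) above annotated genes (grey) at RpL30, rib, the histone array and the 5S rRNA array, drawn to scale along dm6 positions in megabases. Both lists have a peak at an end of RpL30 and inside rib, while the arrays hold 120 and 94 of the 4196 fkh-Gal4 peaks and 15 and 0 of the 907 sage-Gal4 peaks.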

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

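Of the tests in this part, those of pooled housekeeping genes, of highly transcribed genes in the sage-Gal4 list and of clustered peaks were chosen after the results were seen.

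Sequences that the gene comparisons did not use carried peaks. On scaffolds with no assigned position there were 820 fkh-Gal4 and 38 sage-Gal4 peaks, on 439 and 31 scaffolds. The mitochondrial genome had 4 and 1.

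The share of peaks off the major arms differed between the drivers, at 23.5% against 6.06% (odds ratio 4.77). A longer list that reaches weaker sites was tested on the 907 widest fkh-Gal4 peaks, of which 13.9% (11.7 to 16.3) lay off the arms, above the upper bound of 7.82% for the sage-Gal4 list. That outcome had been set beforehand as evidence against list length. The test needs the widest peaks to be the strongest, which lists without a measure of strength cannot show. Of 86 ribosomal protein genes, 2 were bound by those 907 peaks and 55 by the sage-Gal4 list, so the 907 peaks are no counterpart of the sage-Gal4 list. The test therefore cannot decide, and list length and driver cannot be told apart. Reads from multi-copy sequence were tested by clustering on the major arms outside the histone and 5S rRNA arrays: with the fkh-Gal4 list thinned to the sage-Gal4 number of 837 peaks, a mean of 2.53% stood in 20 kb bins with 5 or more peaks (0.836 to 4.90 over 100 draws, 92 of them above the sage-Gal4 upper bound), against 0.597% (0.194 to 1.39) of sage-Gal4 peaks. With the arrays kept, the mean was 7.53% and all 100 draws lay above the sage-Gal4 upper bound of 2.60%, but the arrays had already been seen, so multi-copy reads cannot be told apart from other origins of the peaks off the arms. A biological difference between the drivers in where Rib-GFP binds repeats was not tested and stays open.

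Ribosomal protein genes with a fkh-Gal4 peak had a sage-Gal4 peak more often than other fkh-Gal4 genes, at 89.5% against 31.6%. Constitutive expression alone was not enough for a peak in the fkh-Gal4 list. The pooled proteasome, oxidative phosphorylation and mitochondrial ribosomal protein genes were bound there at 7.54% (15 of 199, 4.28 to 12.1), against 8.55% of all genes. The counts of these lists had been seen before they were pooled, and the pool says nothing about more highly transcribed constitutive genes. Against short genes in gene-dense stretches, 10000 random lists matched on length and number of neighbours held a mean of 3.95 fkh-Gal4 genes, 13 at most, where 57 were observed. Of 26 highly transcribed genes that code for other proteins, 19.2% (6.55 to 39.4) were bound in the sage-Gal4 list, against 4.06% of all genes. That share lay below the ribosomal protein share of 64.0% (52.9 to 74.0). In the fkh-Gal4 list 46.2% were bound (12 of 26, 26.6 to 66.6), against 8.55% of all genes. This overlaps the ribosomal protein share of 66.3% (55.3 to 76.1), so high transcription cannot be told apart there from binding at ribosomal protein genes. In both lists the highly transcribed genes thus had peaks more often than all genes. Their choice rests on textbook knowledge, and no control immunoprecipitation from embryos without the tagged protein was analysed here.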

How the results depend on the processing

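The arrays, gene-body and random-thinning alternatives were chosen after the data were seen. Of the values that answer a comparison, 56 of those recomputed under an alternative stayed on the same side of the threshold or within 1.5 times the reported count. A further 11 counts moved beyond that, 2 values passed with their direction reversed and 2 newly passed in the same direction. The 56 include sizes of the peak lists, which the setting itself fixes and which say nothing about stability. Of the 56, those past the threshold kept their direction. The fkh-Gal4 share at gene ends, which was not past it, turned below rotated peaks without the arrays (24.6%, permutation p = 0.809). The sage-Gal4 share at gene ends (38.5% to 49.8%), the overlap of the peak lists (29.2% to 68%) and that of the bound genes (odds ratio 14.1 to 45.3) kept side and direction under every alternative run. The greater width of shared peaks (22 to 63 bp) did too, but fkh-Gal4 peaks met by rotated peaks were nearly as wide (median 169.5 against 173 bp), and the alternatives have no rotated value, so this is no evidence of stability. For single lists, 123 values stayed on the same side of the threshold. Those past it kept their direction, but some not past it changed direction, such as BTB and Pipsqueak-domain genes in the fkh-Gal4 list with a 500 bp window (5.88%).

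The lists shrank by construction to 2098 and 454 peaks with the wider peaks alone and to 907 with the equal-size list. The fkh-Gal4 share at gene ends passed above rotated peaks when peaks were merged (27.5%, permutation p = 0.032) or the window was 500 bp (22.4%, p = 0.002). It passed below them with a 2 kb window (32.5%, permutation p = 0.026) or the equal-size list (21.4%, p = 0.038); the cause was not tested. Lists passing for fkh-Gal4 fell from 7 to 4 with the wider peaks, 2 with the equal-size list and 2 (median of 100 draws) with random thinning, where fewer peaks were tested. For sage-Gal4 they rose from 3 to 8 with gene bodies, where the 5 added counts lay within the central 95% of length-matched random lists. Lists shared between the drivers more or less often than other genes went from 1 to 2 with the wider peaks, the 500 bp window and the nearest gene end. There histones joined as less often shared (13.5%, 17.1% and 7.95% also in the sage-Gal4 list), and the cause was not tested. The number of such lists went to 0 with the equal-size list, which holds 2 bound ribosomal protein genes and so says nothing about stability. Salivary gland and polarity genes fell below the background, to 0% each, in the equal-size list, and polarity genes to 2.78% with the wider peaks (adjusted exact p = 1 for each). Histones fell to 0% in both lists without the arrays, by construction. For single lists, 9 other calls were lost and 8 gained.

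The searches for 13 motifs were not run at any setting. No paired analysis was possible because each driver has 1 merged list, with no replicate numbers. The read depth behind the lists is unknown, so a site missing from the shorter list is not shown to be unbound.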

Other observations

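Of the tests in this part, those of snoRNA and miRNA genes, of peaks over extended gene bodies and of random thinning were chosen after the data were seen, as were the Enhancer of split and Bearded families and the other named loci.

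Genes for small nuclear and nucleolar RNAs also carried peaks. Within 1 kb of a peak lay 31 of 269 snoRNA genes in the sage-Gal4 list, where rotated peaks gave a mean of 3.68 (adjusted permutation p = 0.01, from the smallest p that rotations give), and 39 in the fkh-Gal4 list against 12.1 (adjusted permutation p = 0.015). In each list 24 of them lay inside or within 1 kb of a bound ribosomal protein gene. The snRNA genes, which make splicing RNAs, were bound at 5 of 32 in the sage-Gal4 list (rotated mean 0.501, adjusted permutation p = 0.0133), all of them U1 or U2 genes, and at 4 of 32 in the fkh-Gal4 list (adjusted permutation p = 0.337). Neither tRNA genes (19 and 3 of 290) nor miRNA genes (8 and 8 of 260) passed in the fkh-Gal4 and sage-Gal4 lists.

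Genes of the Notch pathway appeared in the sage-Gal4 list. Of 15 Enhancer of split and Bearded family genes, 8 were bound there (53.3%, 26.6 to 78.7), with 7 peaks in the Enhancer of split cluster (3R, 25997621 to 26041008) and 1 at Tom. In the fkh-Gal4 list 2 of 15 were bound, with 2 peaks in the cluster. The families were picked after peaks at these genes had been seen and neighbours share peaks, so the counts are given without a test. The difference between the drivers was not tested.

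Several other loci were picked out after their values were seen. Toll-7, a Toll family receptor gene, had a 342 bp fkh-Gal4 peak (2R, 19826330 to 19826671) and a 378 bp sage-Gal4 peak (19826236 to 19826613) across its end. The Hedgehog receptor gene ptc had peaks of 173 bp (2R, 8649460 to 8649632) and 221 bp (8649507 to 8649727), and noc, a zinc finger gene, peaks of 113 bp (2L, 14490800 to 14490912) and 236 bp (14490722 to 14490957).

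Genes of Rib's own family carried peaks along their bodies. With the gene body and 1 kb around it counted, 12 of 17 BTB and Pipsqueak-domain genes had a fkh-Gal4 peak (70.6%, 44.0 to 89.7), among them rib and, named after their values were seen, lola, psq, ttk, Trl, bab1 and bab2, and 7 of 17 a sage-Gal4 peak. These genes are long, with a median of 50.4 kb against 2.16 kb for all genes. Random lists of genes of nearly the same length held a mean of 7.10 with a fkh-Gal4 peak (central 95% 4 to 11, highest 15), and 0.78% of them reached 12. For sage-Gal4 the mean was 3.77 (central 95% 1 to 7), and 5.09% reached 7. The fkh-Gal4 count lies above the central range and below the highest list, so gene length may account for these peaks and cannot be told apart from binding to the family.

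Whether the greater length of the fkh-Gal4 list accounts for its larger number of salivary gland genes cannot be told. Lists thinned at random to 907 peaks bound a mean of 1.91 (0 to 5 over 100 draws), and the sage-Gal4 list bound 2. The same thinning left a mean of 12.3 ribosomal protein genes (6 to 24), against 55 in the sage-Gal4 list. The thinned lists are thus no counterpart of the sage-Gal4 list, and their salivary gland count cannot decide the question. Nor can the 907 widest peaks, which bound 0 salivary gland genes but also few ribosomal protein genes.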
